A study of Mus musculus with 6 samples.

How the data were processed

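RNA from samples labelled as nodose ganglion neurons of mice was measured on Illumina Mouse-6 version 2 expression BeadChips. There was 1 array per sample and 6 arrays in all. The nodose ganglion holds the cell bodies of vagal sensory neurons. Per the labels, neurons were cut out of stained 25 µm cryosections by laser microdissection to separate them from fibers and glia, and each sample was a pool of RNA from several animals of 1 genotype. Biotin-labelled cRNA was prepared with the Ambion MessageAmp kit, per the labels. The 3 control samples came from mice with a Cre recombinase under the Phox2b promoter and 1 floxed Pparg allele. The 3 knockout samples came from mice with the same recombinase and 2 floxed Pparg alleles. Groups and replicate numbers were taken from the sample labels, which call the pools independent biological replicates. The number of animals per pool, and whether an animal gave RNA to more than 1 pool, were not given in the sources used here. Hybridization chip, date and sex of the animals were not given either.

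The deposited table held, for each of 45281 probes and each array, a signal intensity on a linear scale and a detection p-value, per the file headers. The submitters' notes name Partek, with version 6.5 in the series description, but the steps were not given in the sources used here. The deposited intensity columns were titled as not normalized, yet sorted from lowest to highest the 6 columns lay within 0.01 of each other on the log2 scale at 100% of ranks, so they had already been quantile normalized. They had not been background-subtracted, since the lowest value was 79.9 and the median probe of each array lay near 93.6. The deposited detection p-value never rose with signal within an array and moved in steps of 1 in 936, which sets the number of negative control probes behind it. The second deposited table held log2 values that differed from log2 of the intensities by at most 5e-05, with no further centring or scaling, so both tables carry the same measurement and scale, centring and direction are known.

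Background was estimated from the detection p-values and removed with the normal-exponential model of limma version 3.58.1 in R version 4.3.3 (function nec, offset 16), and values were taken to log2. Quantile normalization was not repeated in the main analysis because the design called for missing steps only. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested, which kept 13762 probes (30.4%). The arrays had between 12579 and 13181 such probes each. The number of arrays limits the precision of every value. Probes were named from the platform annotation. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and a comparison by Entrez gene number with a GRCm38.p6 gene table changed 0 symbols. The tested probes with 1 symbol, 11917 in number, named 9005 genes, and the other 1845 tested probes were left unnamed. A gene was counted as changed if any of its tested probes passed.

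The comparison was a limma linear model per probe with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05 on the adjusted p. A second count used an unadjusted p under 0.05 with a fold change of at least 1.5. Where a probe was not above background on any array of a group, the fold was given as a lower bound. The bound set the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes above background on that array. Other differences are log2 values of the arrays labelled knockout minus those labelled control, with the standard error of the limma fit and n = 3 per group. The offset pulls differences of dim probes toward 0.

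The main comparison and its tests, the 27 gene lists and the rule for naming genes were fixed before the data were examined, and tests chosen later are named as such where they are given. Named are Pparg and Phox2b, the 12 genes with the largest log2 difference in each direction among those called (clone, LOC, Gm and RIKEN names passed over, 1 probe among the higher and 4 among the lower), and in each list the called members up to 4 by size of the difference. The 10 largest differences per direction among probes above background on all 6 arrays were added after the values were seen. Lists were tested with camera (limma, preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists) on the brightest tested probe of each gene. Lists of PPAR response, fatty acid oxidation, fatty acid synthesis, cholesterol, electron transport, nuclear receptor, sensory neuron, receptor, neuropeptide, ion channel, other cell type, stress, inflammation, clock, sex-linked and ribosomal protein genes are all reported.

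Alternatives were values without background correction, an offset of 50, the second deposited table, no filter on dim probes, a filter requiring all 6 arrays, the replicate number as a block, array weights, a variance trend with robust moderation, an ordinary linear model, each array left out in turn, and an adjusted p of 0.1. For the lists, an estimated correlation, fry and the mean of all tested probes were also run. Shifting medians in place of quantile normalization could not be run on values already quantile normalized, and no chip was named to serve as a block. On simulated arrays built for this comparison from the control means and the residual spread of 13762 probes, the fit recovered 44% of probes changed 1.25-fold, 90% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold. Of the 176 calls in that simulation 11 were false. Only 50 probes were changed at each of these folds, far fewer than were called in the data, and the simulated arrays of a group shared no error. The recovered and false shares therefore do not carry over to the measured calls.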

Results

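Gene expression was measured in samples labelled as laser-captured nodose ganglion neurons of mice. The question was which transcripts differ when both copies of Pparg can be deleted in cells that have expressed Phox2b. Pparg encodes the lipid-sensing nuclear receptor PPARγ. There were 3 pooled samples labelled control, whose mice had 1 floxed Pparg allele, and 3 pooled samples labelled knockout, whose mice had 2. Each array had between 12579 and 13181 probes above background, out of 45281. Arrays of one group resembled each other far more than arrays of different groups. The SD of the log2 difference over the 13762 tested probes was 0.13 to 0.17 for the 6 pairs within a group and 0.87 to 0.88 for the 9 pairs between groups. Pearson r across probes was 0.997 to 0.998 and 0.907 to 0.908.

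Pparg signal was not lower on the arrays labelled knockout, but no Pparg probe was above background on the arrays labelled control. A fall in Pparg could therefore not have been seen, whatever the deletion did. One of its probes, ILMN_1221060, read 90.3, 92.7 and 93.9 on the arrays labelled control, where it was not above background, and 125, 125 and 118 on the arrays labelled knockout, where it was above background on 3 of 3. On the log2 scale the means were 4.31 ± 0.04 and 5.52 ± 0.14 (SD, n = 3 each), a signal at least 1.77-fold higher on the arrays labelled knockout (limma adjusted p = 1.45e-06). The exact two-sided permutation test of these 3 against 3 values gave p = 0.1, the smallest it can give. The other Pparg probes, ILMN_1221594 and ILMN_1221893, were at background on all 6 arrays, with signals between 88.2 and 95.9. Where these probes lie in the gene was not given, and a probe outside the floxed exons checks nothing about the deletion. The measured probe therefore could not check the labels. Groups are named by their labels throughout, and each direction below rests on those labels. No probe was named Phox2b. Without background correction the log2 difference of the Pparg probe was 0.41 in place of 1.21.

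**Figure D1:**
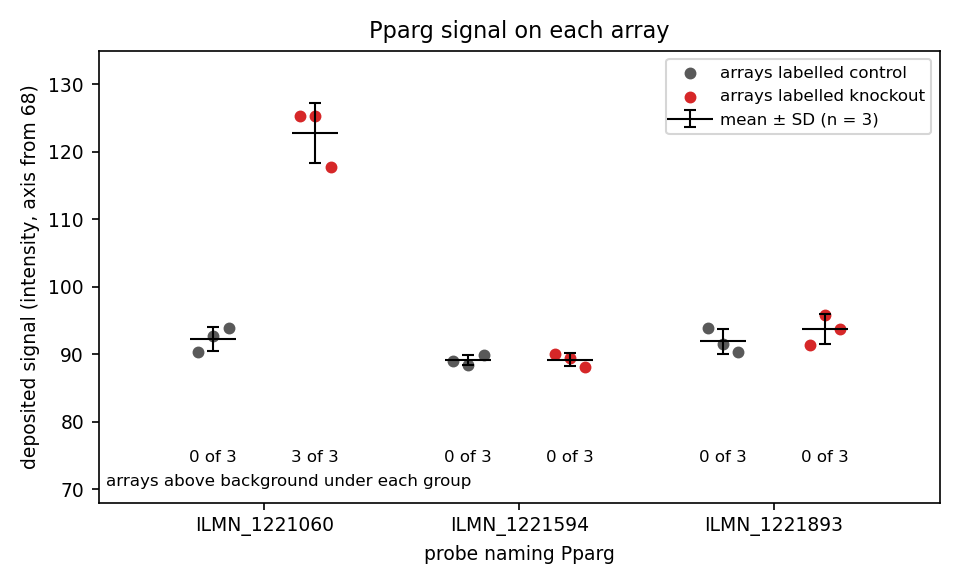
Deposited signal intensity of the 3 probes naming Pparg on each of the 6 arrays, with points for arrays, bars for the mean ± SD (n = 3) and, beneath, the number of arrays above background. ILMN_1221060 lies between 90.3 and 93.9 on the arrays labelled control and between 118 and 125 on those labelled knockout, and the other probes stay at background.

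The arrays labelled knockout carried higher signal for Parp14, an ADP-ribosyltransferase (log2 difference 3.72 ± 0.12 SE, n = 3 per group), for Ikbip (3.42 ± 0.06) and for Mtf1, the metal-responsive transcription factor (3.50 ± 0.06, above background on 2 of 3 arrays labelled control). Several other genes had probes above background on the arrays labelled knockout only. Sh3d21 was at least 13.9-fold higher, the nucleoporin gene Nupl1 at least 14.2-fold, and the O-glycan synthase gene C1galt1 at least 9.82-fold. Parp3 was at least 8.90-fold higher, Zfp597 at least 9.19-fold, Cmtm4 at least 8.77-fold, the protease inhibitor gene Spink1 at least 8.48-fold and Smpdl3b at least 8.30-fold. Appl1, which encodes an endosomal adaptor protein, was higher by 3.31 ± 0.05. Its 2 other tested probes gave 3.25 and -0.45, the latter called in the opposite direction. In the other direction, Angel2 fell by 4.50 ± 0.10 and Mycbp fell by 3.73 ± 0.05, both still above background on all 6 arrays. Probes above background on the arrays labelled control only included the calcium/calmodulin-dependent kinase gene Camk2d (at least 16.6-fold lower on the arrays labelled knockout), Cep112 (18.1-fold), Dock4 and Sntb2 (14.6-fold each), and Mrpl15 (14.1-fold). They also included Uqcrq (12.5-fold), Dlst, a subunit of the 2-oxoglutarate dehydrogenase complex (12.2-fold), Ric1 (11.6-fold), Mtap (10.3-fold) and the protocadherin gene Pcdh10 (10-fold), all as lower bounds. Adjusted p-values of these genes lay between 1.93e-09 and 4.16e-08 (limma).

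Other probes of the same gene often gave a smaller difference. Those of Angel2 gave -0.58 and -0.26, those of Camk2d -0.41 and -0.39, those of Mtf1 0.39 and 0.50, that of C1galt1 0.33 and that of Ikbip 0.30. The other probes of Nupl1 (2.67), Cmtm4 (2.15), Mycbp (-3.40) and Mtap (-2.50) came closer to the probe named above, though still smaller in size. The 3 other probes of Dlst ranged from -3.17 to -0.27. Those of Dock4 gave -1.74 and -0.06, the latter not called, and those of Mrpl15 gave 0.06 and 0.07 and were not called. Those of Pcdh10 gave 0.33 and 1.81, both called in the opposite direction. Among probes above background on all 6 arrays, the largest differences after Parp14, Ikbip and Appl1 were in Tmem128 (3.23 ± 0.06, with its other probe at -0.44), the sulfation enzyme gene Papss2 (3.16 ± 0.08) and Dennd2a (3.10 ± 0.08). Next came Epb41l4a (3.05 ± 0.07), Taf1a (3.04 ± 0.09), Gatd3a (2.78 ± 0.05) and Pip5k1b (2.74 ± 0.05). The largest in the other direction after Angel2 and Mycbp were in Tril (-3.69 ± 0.07), Trim9 (-3.38 ± 0.06), Rbm11 (-3.38 ± 0.05) and Tbc1d2 (-3.25 ± 0.05, and -1.61 with its other probe). Next came the signalling adaptor gene Traf6 (-3.23 ± 0.05, and -2.81 with its other probe), Glrx3 (-3.22 ± 0.08, and -0.47 and -0.29 with its other probes), Papolg (-2.95 ± 0.06) and Mrgpra2b (-2.95 ± 0.05, with its other probe at -0.04 and not called). These lists of 10 genes per direction were chosen after their values were seen.

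In all, 7223 of 9005 genes tested (80.2%) differed between the groups at an adjusted p under 0.05 (limma). Of these 3951 had a probe higher and 3676 a probe lower on the arrays labelled knockout, and 404 had probes called both ways. Differences of at least 2-fold were called in 2156 genes, 1106 higher and 1087 lower, and differences of at least 4-fold in 385. An unadjusted p under 0.05 with a fold change of at least 1.5 was met by 4301 genes, and by 2080 without background correction. The 3 values of one group lay wholly above those of the other for 78.1% of tested probes, where chance gives 10%. The median absolute difference was 0.48 on the log2 scale against a median SD within groups of 0.08, and the median signed difference was 0.02. The deposited values were already quantile normalized, so a general shift of one group could not have been seen. The small median and the near balance of higher and lower calls follow in part from that step. Of the tested probes 1971 were above background on every array of one group and none of the other, 1052 of them on the arrays labelled knockout and 919 on those labelled control. A limma test against a 1.5-fold change, chosen after seeing the data, called 3233 genes, 1694 higher and 1600 lower. All these counts, p-values and standard errors take the 3 arrays of a group as separate pools, as labelled. If the arrays of a group carried portions of 1 amplified RNA, the p-values would measure variation between arrays only. They would then not test a difference between the genotypes.

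**Figure D2:**
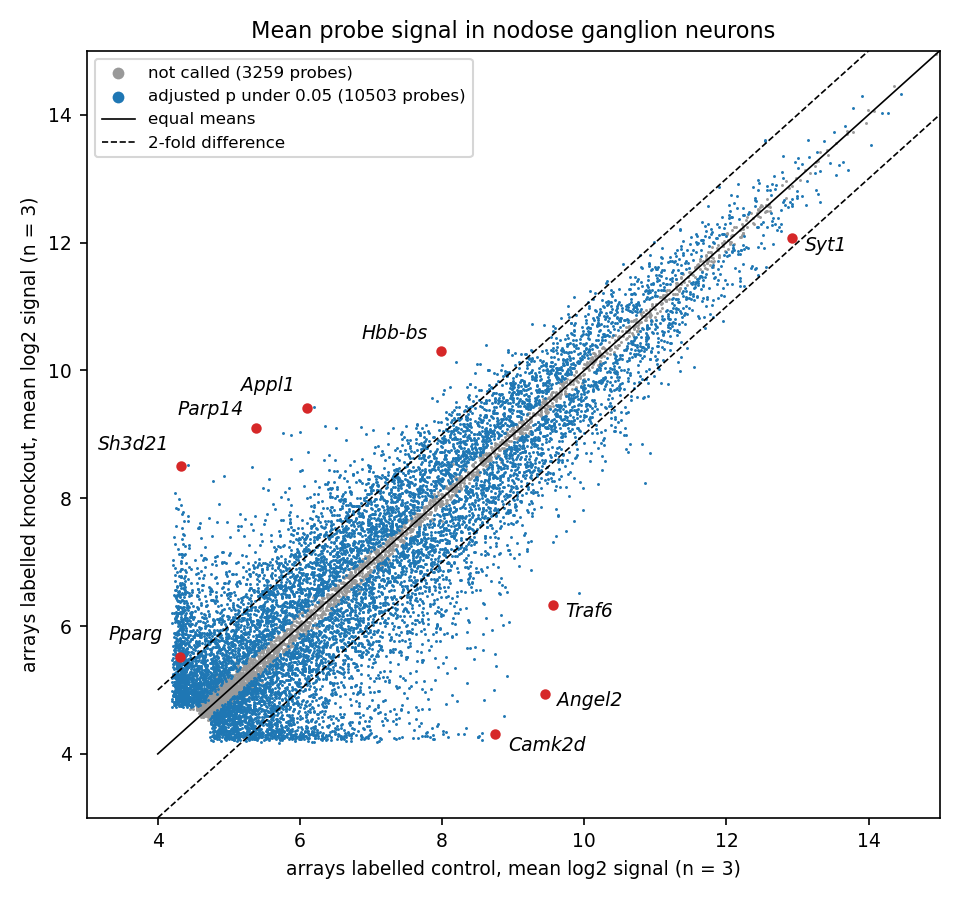
Mean background-corrected log2 signal of the 13762 tested probes on the 3 arrays labelled control (x axis) and the 3 labelled knockout (y axis), with called probes in blue, other probes in grey and some named genes in red. The 10503 called probes lie on both sides of the line of equal means, and many reach beyond the dashed lines of a 2-fold difference.

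Genes of the mitochondrial respiratory chain, of the ribosome and of red blood cells passed as groups with the preset correlation, each higher on the arrays labelled knockout. None of the 3 calls held with an estimated correlation (camera adjusted p = 0.266 for each). The estimates lay below the preset 0.01 (0.0055 for electron transport, -0.0113 for ribosomal proteins and -0.0256 for erythrocytes). A stronger correlation between members was therefore not what raised the adjusted p. With an estimated correlation camera takes its degrees of freedom from the 6 arrays, and with the preset from the number of genes. The test with an estimate is thus less sensitive when arrays are few. Of 63 measured electron transport and ATP synthase genes 38 rose, 11 fell and 14 did not pass, with a median log2 difference of 0.31 (camera adjusted p = 0.0320, and 0.266 with an estimated correlation). Members that rose included the complex I genes Ndufs8 (1.26 ± 0.06) and Ndufa6 (1.06 ± 0.07) and Cox7a2l (1.16 ± 0.11), while the complex III gene Uqcrq was at least 12.5-fold lower. Of 40 ribosomal protein genes 28 rose, 7 fell and 5 did not pass, with a median of 0.32 (camera adjusted p = 0.0477, and 0.266 with an estimated correlation). That median lay at percentile 92.8 of random lists matched on mean signal and genomic span. Rpl13a (1.23 ± 0.06), Rps10 (1.00 ± 0.05) and Rps6 (1.00 ± 0.10, above background on 1 of 3 arrays labelled control) rose, and Rpl4 fell by 2.90 ± 0.11 (above background on 1 of 3 arrays labelled knockout). The measured erythrocyte genes rose in 5 of 5 cases, with a median of 1.94, or 1.81 with genes at background set at their bounds and 1.10 without background correction (camera adjusted p = 0.0320, and 0.266 with an estimated correlation). The medians of the electron transport and ribosomal lists were 0.31 and 0.32 with such bounds too. The erythrocyte genes were the globin genes Hbb-bs (2.32 ± 0.06), Hba-a1 (1.94 ± 0.05) and Hbb-bt (1.74 ± 0.06), the anion exchanger gene Slc4a1 (at least 3.52-fold) and Alas2 (at least 2.36-fold), which encodes the erythroid enzyme of heme synthesis. Alas2 was named after its values were seen. As markers of 1 cell type, these 5 genes are not independent cases. The correlation estimates rest on arrays within a group and could not show variation between pools if those arrays shared RNA. Adjusted over the list alone, 49 electron transport, 35 ribosomal protein and 5 erythrocyte genes were called. Across genes, the shortest 20% by genomic span were higher on the arrays labelled knockout in 58.5% of cases and the longest 20% in 44.0%. The median spans were 7510 bp for the electron transport list and 3452 bp for the ribosomal list against 22555 bp for all measured genes. Leaving out control replicate 1, 2 or 3 ended the electron transport call (adjusted p = 0.0569, 0.0822 and 0.0839) and the ribosomal call (0.174, 0.132 and 0.153), and leaving out control replicate 2 ended the erythrocyte call (0.0507), as did keeping only probes above background on all 6 arrays (0.0578). The replicate number as a block ended the ribosomal call too (0.0561). With an array labelled knockout left out, the electron transport (0.00452 to 0.0112) and ribosomal (0.0396 to 0.0476) calls stayed. Leaving out an array also changed the genes tested, since probes above background only in its group then missed the filter. Genes called higher and lower numbered 3894 and 3018 without control replicate 1, and 3102 and 3531 without knockout replicate 1. Over all alternatives the adjusted p reached 0.266. The lowest values, 5.89e-05 for electron transport, 3.53e-06 for erythrocytes and 5.00e-06 for ribosomal proteins, came from fry, which tests a list against no change and not against other genes.

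**Figure D3:**
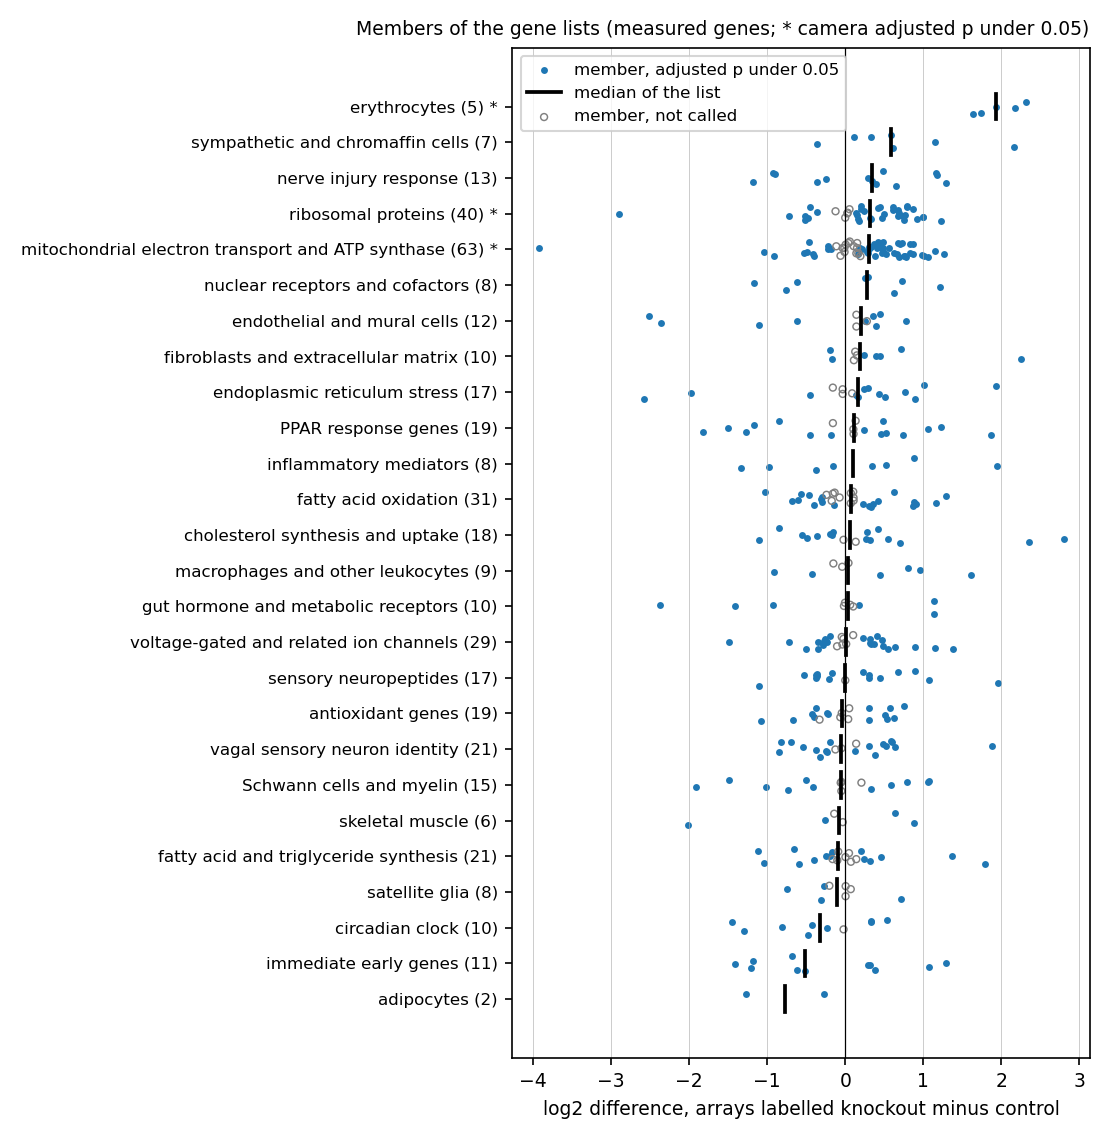
Log2 difference (arrays labelled knockout minus arrays labelled control, n = 3 each) of every measured member of the gene lists with at least 2 measured genes, 1 point per gene, filled where the limma adjusted p was under 0.05, with a bar at the median of each list. Numbers of measured genes are in parentheses. The erythrocyte list has the highest median, 1.94, and most other lists have called members on both sides of 0.

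Of all 9005 genes, taken with 1 probe each, 77.4% were called and 51.0% had a higher mean on the arrays labelled knockout. The member counts of every list stand against these shares. Genes known to respond to PPAR receptors went both ways. Of 19 measured, 8 rose, 7 fell and 4 did not pass, and 16 were called when adjusted over the list alone. The lipid droplet gene Plin4 was at least 2.93-fold higher on the arrays labelled knockout. Pdk4, which encodes a kinase that restrains pyruvate oxidation, fell by 1.82 ± 0.07, the fatty acid transporter gene Slc27a1 fell by 1.51 ± 0.07 and Cidea fell by 1.27 ± 0.08. The median of the list was 0.11, its mean -0.02 and its camera adjusted p 0.983, with the test pointing up. Fatty acid oxidation genes split as 11 higher, 10 lower and 10 not passed of 31 (21 adjusted over the list alone, median 0.07, camera adjusted p = 0.983). Scp2 (1.29 ± 0.06), Acads (1.17 ± 0.07) and the carnitine carrier gene Slc25a20 (0.91 ± 0.08) were higher and Eci1 was lower (-1.03 ± 0.05). Fatty acid and triglyceride synthesis genes split as 6 higher, 8 lower and 7 not passed of 21 (10 adjusted over the list alone, median -0.09, camera adjusted p = 0.983). The elongase genes Elovl6 (1.79 ± 0.05) and Elovl1 (1.36 ± 0.07) were higher, malic enzyme Me1 was lower (-1.12 ± 0.12) and Gpam was at least 1.59-fold lower. Cholesterol genes split as 8 higher, 8 lower and 2 not passed of 18 (16 adjusted over the list alone, median 0.06, camera adjusted p = 0.983). Nsdhl was at least 5.42-fold and the sterol carrier gene Stard4 at least 3.80-fold higher, while Lss (-1.10 ± 0.05) and the transcription factor gene Srebf2 (-0.85 ± 0.07) were lower. Of 8 nuclear receptor and cofactor genes 5 rose and 3 fell (8 adjusted over the list alone, median 0.28, camera adjusted p = 0.983). Besides Pparg these included Rxrb (0.72 ± 0.05), Rxrg (-0.76 ± 0.09) and the liver X receptor gene Nr1h3, at least 1.66-fold lower.

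Genes of sensory neurons also changed in both directions, as did genes across the arrays (77.4% called, 1 probe per gene). Of 21 vagal sensory neuron genes 9 rose, 9 fell and 3 did not pass (18 adjusted over the list alone), with a median of -0.05, a mean of 0.06 and a camera test pointing down (adjusted p = 0.983). The neurotrophin receptor gene Ntrk2 rose by 1.88 ± 0.11, and the synaptic vesicle gene Syt1 (-0.85 ± 0.05), the neurofilament gene Nefm (-0.70 ± 0.08) and the capsaicin receptor gene Trpv1 (-0.82 ± 0.10, above background on 1 of 3 arrays labelled knockout) were lower. Among 10 gut hormone and metabolic receptor genes 3 rose, 3 fell and 4 did not pass (6 adjusted over the list alone), with a median of 0.03, a mean of -0.21 and a camera test pointing down (adjusted p = 0.983). The insulin receptor gene Insr fell by 1.41 ± 0.05 and Igf1r fell by 2.38 ± 0.07, though another Igf1r probe was called the other way, and Htr3a (1.14 ± 0.06) and Sstr2 (1.13 ± 0.05) rose. Of 17 neuropeptide genes 8 rose, 8 fell and 1 did not pass (16 adjusted over the list alone, camera adjusted p = 0.983). The dynorphin precursor gene Pdyn was at least 2.87-fold higher, Sst (1.07 ± 0.06) and Scg2 (0.89 ± 0.06) were higher, and the natriuretic peptide gene Nppb was at least 1.58-fold lower. Of 29 ion channel genes 13 rose, 10 fell and 6 did not pass (23 adjusted over the list alone, median 0.01, camera adjusted p = 0.983). Asic1 (1.38 ± 0.06), Hcn3 (1.15 ± 0.05) and Kcnt1 (0.90 ± 0.07) were higher and the sodium channel subunit gene Scn3b was at least 2.24-fold lower. Hcn3 and Kcnt1 each had another probe called the other way. The median of the neuropeptide list was 0.00 and, like that of the ion channel list, changed sign without background correction.

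Markers of other cell types in and around the ganglion were called too, as were 77.4% of all genes (1 probe per gene). Of their lists only that of erythrocytes passed camera with the preset correlation, and it did not with an estimated correlation (adjusted p = 0.266), without control replicate 2 (0.0507) or with probes above background on all 6 arrays (0.0578). Satellite glia genes (8 measured, 1 higher and 3 lower, 4 adjusted over the list alone) included Sox10 (-0.74 ± 0.05), Apoe (0.72 ± 0.08), Gja1 (-0.31 ± 0.05) and Ednrb (-0.27 ± 0.05). Schwann cell and myelin genes (15 measured, 5 higher and 6 lower, 11 adjusted over the list alone) included Drp2 (-1.91 ± 0.07), Fa2h (-1.49 ± 0.07), Egr2 (1.07 ± 0.06) and Mbp (1.07 ± 0.05). Fibroblast and matrix genes (10 measured, 5 higher and 2 lower, 7 adjusted over the list alone) had a median of 0.19. They included Col6a1 (2.26 ± 0.07, above background on 1 of 3 arrays labelled control), Mgp (0.71 ± 0.07), Dcn (0.44 ± 0.06) and Serpinf1 (0.40 ± 0.05). Endothelial and mural genes (12 measured, 5 higher and 4 lower, 9 adjusted over the list alone) had a median of 0.20, a mean of -0.32 and a test pointing up. They included Flt1 (-2.51 ± 0.06), Cspg4 (-2.36 ± 0.07, above background on 2 of 3 arrays labelled knockout), Acta2 (-1.11 ± 0.05, with another probe called the other way) and Emcn (0.78 ± 0.07). Leukocyte genes (9 measured, 4 higher and 2 lower, 6 adjusted over the list alone) included the antigen presentation genes H2-Aa (1.61 ± 0.10) and Cd74 (0.96 ± 0.07), the T cell gene Cd3e (0.81 ± 0.06) and Laptm5 (-0.91 ± 0.05). Sympathetic and chromaffin cell genes rose in 6 of 7 cases with 1 lower (7 adjusted over the list alone) and a median of 0.58, or 0.35 with bounds. Among them were Gata2 (at least 3.51-fold), the catecholamine synthesis genes Dbh (at least 1.97-fold) and Th (0.62 ± 0.05), and Slc6a2 (at least 1.27-fold). Skeletal muscle genes (6 measured, 2 higher and 2 lower, 4 adjusted over the list alone) included Tnnt1 (-2.01 ± 0.07), Myl1 (0.88 ± 0.05), Pvalb (0.63 ± 0.06) and Des (-0.26 ± 0.07). Of the adipocyte genes 2 were measured, Cidea and Lep (-0.27 ± 0.07), both lower (2 adjusted over the list alone). Camera gave adjusted p = 0.282 for the sympathetic list, 0.688 for the fibroblast and adipocyte lists and 0.983 for the satellite glia, Schwann cell, endothelial, leukocyte and muscle lists. Of the sex-linked genes Eif2s3y was measured, with its brighter probe lower (-1.03 ± 0.10) and its other probe at 0.07 and not called. No Xist probe was above background on any array.

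Stress and activity genes showed large single changes in both directions, where 77.4% of all genes were called (1 probe per gene). None of their lists passed camera, which compares a list with other genes, while fry, which does not, called each of them (adjusted p between 0.000272 and 0.0304). Among 11 immediate early genes 5 rose and 6 fell (11 adjusted over the list alone, median -0.52, camera adjusted p = 0.983). Egr1 (-1.41 ± 0.05) and Jun (-1.19 ± 0.07) were lower, Fos was at least 1.98-fold lower and Atf3 at least 1.94-fold higher. Of 13 nerve injury genes, which share Atf3 and Jun with that list, 8 rose and 5 fell (13 adjusted over the list alone, median 0.35, camera adjusted p = 0.983). Arg1 (1.18 ± 0.05) and Flrt3 (1.17 ± 0.10) were among those that rose. Of 8 inflammatory genes 4 rose and 4 fell (8 adjusted over the list alone, median 0.09, or -0.06 with genes at background set at their bounds, camera adjusted p = 0.983). The chemokine genes Cxcl1 (at least 2.84-fold) and Cxcl12 (0.88 ± 0.05) were higher, the interferon-induced gene Ifit3 (-1.33 ± 0.07) was lower and Stat3 was at least 1.66-fold lower. Of 19 antioxidant genes 7 rose, 7 fell and 5 did not pass (14 adjusted over the list alone, median -0.04, camera adjusted p = 0.983). Among them were Prdx3 (-1.08 ± 0.07), Gpx3 (0.76 ± 0.05), catalase gene Cat (-0.67 ± 0.11) and Keap1 (0.63 ± 0.07). Of 17 endoplasmic reticulum stress genes 10 rose, 3 fell and 4 did not pass (13 adjusted over the list alone, median 0.17, or 0.14 with bounds, camera adjusted p = 0.882). The stress sensor gene Ern1 (-2.58 ± 0.06) and Chac1 (-1.98 ± 0.07) were lower, and Creld2 (at least 3.03-fold) and Pdia4 (at least 1.66-fold) were higher. Of 10 circadian clock genes 3 rose, 6 fell and 1 did not pass (9 adjusted over the list alone, median -0.32, or -0.30 with bounds, camera adjusted p = 0.810). Clock (-1.45 ± 0.06), Cry2 (-1.29 ± 0.11) and Tef (-0.80 ± 0.10) were lower and Per2 (0.53 ± 0.09) was higher.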

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

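The repeat of quantile normalization after background removal and the test against a 1.5-fold change were chosen only after the result was seen. The count of 7223 changed genes lay between 6342 and 6605 with each array left out in turn and between 3233 and 7705 over all alternatives. Only the test against a 1.5-fold change moved it by more than 1.5 times, to 3233, with 1694 higher in place of 3951 and 1600 lower in place of 3676, as a larger difference is then required. The 4301 genes past the unadjusted threshold became 2080 without background correction and 2080 with the second deposited table, which holds the same values on the log2 scale, and between 3752 and 3843 with an array left out. The Pparg probe kept its direction and its call in each of the 12 alternatives that tested it (log2 difference 0.41 to 1.23). It was not tested when an array labelled knockout was left out or when all 6 arrays had to be above background, because it then missed the filter.

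With an estimated correlation the adjusted p was 0.266 for the electron transport, the erythrocyte and the ribosomal lists. With an array left out it lay between 0.00452 and 0.0839 for electron transport, between 0.0396 and 0.0507 for erythrocytes and between 0.0396 and 0.174 for ribosomal proteins, where fewer arrays and, through the filter, other probes were tested. With only probes above background on all 6 arrays it was 0.0578 for erythrocytes. Without background correction the median log2 difference of the erythrocyte list was 1.10 in place of 1.94. Over all alternatives the lowest adjusted p came from fry, 5.89e-05 for electron transport, 3.53e-06 for erythrocytes and 5.00e-06 for ribosomal proteins. The highest was 0.266 for each list, from camera with an estimated correlation. Fry, which asks whether the genes of a list move one way and does not compare them with other genes, called 23 of 26 lists. The same-numbered replicates of the 2 groups did not deviate together (correlations of deviations across probes -0.00, 0.02 and -0.05). With the replicate number as a block, 7164 genes were called, 3917 higher and 3646 lower, and the ribosomal list had an adjusted p of 0.0561. Among the lists and named genes the block changed no other call.

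The 137 probes of named genes and list members kept direction and side of the threshold in 2042 of 2042 values, which come from the alternatives in background, offset, table, filter, model, arrays and quantile normalization. These probes were chosen as called, and by size of the difference, in the same data, so this outcome was close to fixed in advance. It says little about other genes. The values without background correction and the second deposited table are 1 measurement counted under both names. The test against a 1.5-fold change and the adjusted p of 0.1 were not applied to them singly. The filter requiring all 6 arrays left 95 of them, and leaving out an array 117 or 121. Shifting medians in place of quantile normalization and a block for the chip were not run. Signal over background limits the folds of dim probes, many of which are lower bounds.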

Other observations

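The tests of the rarer transcripts and both tests of the Pparg probe were chosen only after the result was seen. The genes were also grouped by the stem of their names, leaving out the electron transport and ribosomal lists, to ask whether families with at least 15 measured genes moved together. Of 52 such families camera called 0, with the preset as with the estimated correlation, and 0 had an unadjusted p under 0.05. The smallest camera p-value (limma) belonged to the centrosomal Cep genes, of which 6 rose and 14 fell among 22 (median -0.46, adjusted p = 0.945). Next came the vacuolar sorting Vps genes, 16 higher and 7 lower of 29 (median 0.16, adjusted p = 0.945), and the mitochondrial ribosomal Mrps genes, 15 higher and 7 lower of 28 (median 0.23, adjusted p = 0.945).

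The groups differed at most probes while the 3 arrays of each were nearly alike, and an effect of the genotype was not tested apart from the explanations that follow. If the arrays of a group carried portions of 1 amplified RNA, erythrocyte, leukocyte and immediate early genes, which follow the state of a dissection, would vary no more within groups than other genes, and the ratio of their within-group SD to that of probes of matched signal was 0.985 (95% bootstrap interval 0.730 to 1.26, 25 genes), which is in line with shared RNA, although pooling of animals may level such genes too. If transcripts of low abundance were gained or lost at random in a small captured sample, large differences would be rarer among bright probes, and among probes above background on all 6 arrays the share of differences of at least 2-fold in the brightest 20% was 0.246 times that in the middle 20% (6.54% against 26.6%, ratio 0.193 to 0.312 from the binomial bounds of both shares). The share was also low in the dimmest 20%, 5.31%, but that value cannot decide the question. Mean log2 signals there ran from 4.77 to 5.69, and the lowest values above background lay at 4.65 to 4.72. This floor and the offset leave little room for a 2-fold difference. Requiring all 6 arrays also removes transcripts lost from a group, so random gain or loss was left undecided. Effects of single probes were left undecided. The log2 differences of 2 probes of one gene had a Pearson r of 0.513 across 1594 genes (95% bootstrap interval 0.462 to 0.563, genes not being independent replicates). Of the 1029 pairs with both called, 80.8% had one direction. Of 368 pairs with a difference of at least 2-fold in a probe, 78.3% had one direction, but only 27.7% had the other probe changed as much the same way.

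The Pparg probe that was measured read higher on the arrays labelled knockout. A signal at background level is argued against, since its detection p-values there were at most 0.00107 and all 3 Pparg probes were looked at whether or not they passed the filter. Whether the labels of the 2 groups were exchanged cannot be told apart from a probe that lies outside the deleted exons, as the tables give the place in the gene for 0 Pparg probes. A change in the remaining transcript of the floxed gene was not tested.

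Genes of the electron transport and ribosomal lists are short, and short genes were higher on the arrays labelled knockout (Spearman rho of log2 difference and genomic span -0.121 across 8994 genes, which are not independent replicates). Among 10000 random lists matched on mean signal and genomic span, the electron transport median of 0.31 lay at percentile 99.3, outside their central 95% (-0.05 to 0.26). That position argues against signal and genomic span as the whole source. Transcript length was not matched, and lists of genes drawn singly carry no correlation between members. The ribosomal median of 0.32 lay at percentile 92.8, inside the central 95% (-0.02 to 0.37), so its height may follow from signal and genomic span alone. Both lists lost their call with an estimated correlation, although the estimates (0.0055 for electron transport and -0.0113 for ribosomal proteins) lay below the preset 0.01. An effect of the genotype was not tested apart from signal and length.

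The labelled split of the 6 arrays gave 7223 changed genes, and the highest of the other splits gave 0 (limma), so 1 of 10 splits gave as many. For genes past the unadjusted threshold the values were 4301 and 2, and for lists called by camera they were 3 and 1, again with 1 of 10 splits as high. With 10 splits a share under 0.05 cannot be reached. Each of the other splits also mixed the labelled groups, so the large difference between these entered the residual spread and pushed the counts toward 0. The low counts therefore do not show what unrelated arrays would give.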
